A study of Spodoptera frugiperda with 2 samples.

How the data were processed

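Small RNA libraries were made from immunoaffinity purified recombinant hAgo2 and from total RNA of Sf9 cells. Per the labels' protocols, RNA was extracted with TRIZOL, size-selected on denaturing gels (19 to 25 nt after radioactive end labelling for hAgo2, 19 to 29 nt for total RNA), cloned by linker ligation and sequenced on an Illumina Genome Analyzer. The labels put 1 library in each group.

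The deposited values were read counts per distinct sequence and depth-scaled reads (RPM), per the file headers. The authors' RPM values equalled the deposited counts divided by rounded library totals, 4030000 for hAgo2 and 5770000 for total RNA, and summed to 100.2% and 99.97% of their nominal total. They served only as a check, and every result here came from the counts. How linkers were trimmed, which reads were filtered and whether reads were aligned is not given in the sources used here. The shortest listed sequence was 7 nt in the hAgo2 library and 15 nt in the total library, and the longest 35 and 34 nt, which a difference in trimming or filtering would give. Trimming sets the measured length directly, and a filter on length or copy number changes shares. Sequences seen once were 74.3% and 77.5% of the distinct sequences. No genome of the organism was used, so reads were classified by sequence matches alone and no genome coordinates are given.

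Comparisons used reads of 19 to 25 nt, the window that both gels share. Depth in that window was 3766103 hAgo2 and 3622365 total reads, so a floor of 3 counts equals 0.797 and 0.828 RPM. RPM printed here were recomputed over the reads of 19 to 25 nt of the same library. Shares carry exact binomial (Clopper-Pearson) 95% intervals, ratios of shares the Katz log interval, and single microRNAs the exact interval of the ratio given the sum of both counts. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only, and differences between cultures, purifications or clonings are not in them.

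The microRNA list held 68 mature sequences under 62 names of microRNAs conserved among insects, entered by hand largely in their fruit fly forms. A read was assigned when it began within 2 nt of the mature 5′ end with at most 1 mismatch over the first 20 mature positions, taking the best placement. With this list 36.6% of the assigned hAgo2 reads and 38.9% of the assigned total reads had no mismatch, and microRNAs particular to moths are not counted. Named microRNAs had at least 100 reads over both libraries and were the 10 most abundant of either library or the 10 with the largest log2 ratio in each direction, at 1 or above in size with an interval excluding 0. That gave 16 names. The 5 most abundant sequences of each library were also examined and printed only where they matched the list. The position of the list was its median log2 ratio (pseudocount 0.5) among 10000 random lists of sequences matched on abundance, a description of these libraries. Structural RNA was counted by exact matches to 11 stretches, and vector RNA by exact matches to 2 stretches (336 nt of the AGO2 coding sequence, 92 nt of the polyhedrin leader) on either strand. 9 vertebrate microRNAs and 2 size-marker oligonucleotides were counted as contaminant lists; the listed markers took 0 reads, while a marker sequence noticed afterwards took 2982 hAgo2 and 11945 total reads of all lengths, and a 3′ linker sequence noticed afterwards took 925 and 2.

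The window, lists, shares and naming rule were set before the data were examined. The following steps were added afterwards. Reads of 20 and 21 nt were joined by greedy extension of 16 nt words with at least 5 reads and 4 times the next best extension, and contigs of at least 50 nt were kept. Contigs with under 1% as many total library reads as hAgo2 reads were called lacking in the total library. Contigs were searched by tblastn (BLAST 2.17.0, E-value limit 0.001) with 5 proteins and their reversed forms. Overlaps between the 5′ ends of reads on opposite strands were counted, first bases of structural fragments were set against their templates, and base shares of contig reads were set against all 20 nt sites of the contigs.

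Tested on simulated data, the assignment recovered 100% of 1334 microRNA reads without a mismatch and 99.9% of 1333 with 1 mismatch, and assigned 1 of 300000 random reads. The assembly covered 84.6% of a simulated 20000 nt template, with 0 of 198 contigs holding an error. The overlap count found partners for 36.5% of 48000 simulated reads at the planted 10 nt overlap and 1.12% at 11 nt. This set was smaller than the 207272 distinct sequences counted below, so its level of chance matches does not carry over. A simulated list of 40 shifted down lay at percentile 0, and at 82.3 unshifted. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

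Alternatives included counting each distinct sequence once, a minimum of 2 reads, leaving out the 10 most abundant sequences of each library (from that library only), the 21 to 23 nt window and other matching rules. The hAgo2 library came from cells that made the recombinant protein and the total library from cells labelled control. Baculovirus gene reads were found in the hAgo2 library alone. Association with hAgo2 and the state of the cells, with or without virus, thus changed together and cannot be told apart.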

Results

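Small RNAs were sequenced from Sf9 cells, an ovarian cell line of the fall armyworm Spodoptera frugiperda that is widely used to make recombinant proteins. 1 library held the small RNAs that came down with recombinant human Argonaute-2 (hAgo2, the slicing Argonaute of the RNA-induced silencing complex) after immunoaffinity purification from these cells. The other library held size-selected total small RNA of Sf9 cells whose transgene label reads control. Each group thus had 1 library and no replicate, so no test between groups was possible and every interval below covers counting error only. The hAgo2 library held 4036552 reads of 1142661 distinct sequences, and the total library 5768169 reads of 1192629. Gels had been cut at 19 to 25 nt for the hAgo2 RNA and at 19 to 29 nt for the total RNA. Comparisons therefore used reads of 19 to 25 nt, which numbered 3766103 (93.3%) in the hAgo2 library and 3622365 (62.8%) in the total library.

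The first comparison set the sizes of the RNAs on the human protein against those of total small RNA, the contrast that the series design names. RNAs of 20 nt dominated the hAgo2 library, where they made up 73.2% of reads (95% interval 73.1 to 73.2), against 23.7% in the total library, a 3.08-fold difference. RNAs of 21 to 23 nt, the size range of insect microRNAs, made up 16.7% of hAgo2 reads and 60.0% of total reads, 3.60-fold lower (log2 ratio −1.85, 95% interval −1.85 to −1.85). At 22 nt, the commonest length of the total library, the shares were 3.36% and 27.3%. With each distinct sequence counted once, the log2 ratio turned to 0.0076 for the 21 to 23 nt share and was 0.18 for the 20 nt share. Without reads of contigs that the total library lacked (described further on), the log2 ratio for 21 to 23 nt was −1.11.

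Reads beginning with A were 2.54-fold more frequent in the hAgo2 library, at 35.3% against 13.9%. Reads beginning with U, the usual first base of microRNAs, made up 38.9% of hAgo2 reads and 51.6% of total reads (log2 ratio −0.41, 95% interval −0.41 to −0.40). C began 14.6% of hAgo2 reads and 27.4% of total reads, and G began 11.3% and 7.08%. With reads of listed microRNAs set aside, the log2 ratio for U was −0.076, and with each distinct sequence counted once that for A was 0.46.

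**Figure D1:**
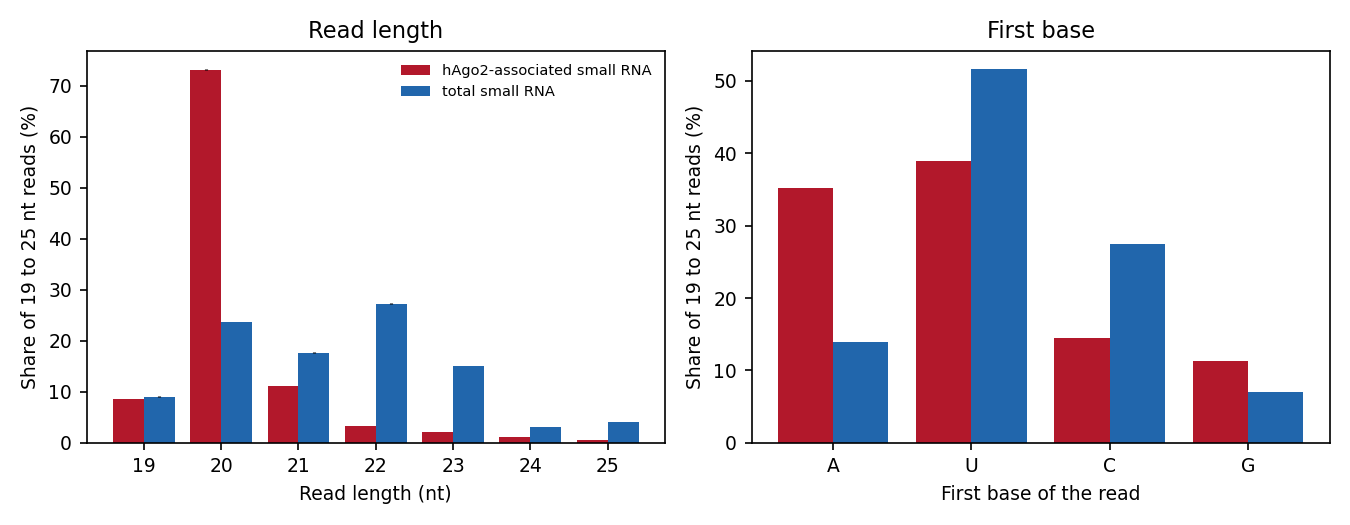
Shares of 19 to 25 nt reads (%) by read length in nt (left) and by first base (right) in the hAgo2-associated library (red) and the total library (blue), 1 library each, with exact 95% intervals on the length bars that are narrower than the lines at this scale. RNAs of 20 nt made up 73.2% of hAgo2 reads and 23.7% of total reads, and A began 35.3% and 13.9%.

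Conserved insect microRNAs were scarce on the human protein. The 62 listed microRNAs took 16306 hAgo2 reads, 0.433% (95% interval 0.426 to 0.440), and 749882 total reads, 20.7% (95% interval 20.7 to 20.7). The share was 47.8-fold lower in the hAgo2 library (95% interval 47.1 to 48.6; log2 ratio −5.58). Reversed forms of the same sequences took 0 reads in either library. Of the 28 microRNAs with at least 100 reads over both libraries, 27 were at least 2-fold lower in the hAgo2 library, 0 were at least 2-fold higher and 1 was neither. Their median log2 ratio was −5.32, with quartiles of −5.92 and −4.83. The log2 ratio of the microRNA share was −3.84 within the 21 to 23 nt window, −4.43 without reads of contigs that the total library lacked, and −2.42 with each distinct sequence counted once. Among all sequences with at least 10 reads, the median of the 38 microRNAs tested this way, −5.47, lay below those of all 10000 random lists matched on abundance, whose middle 95% ran from −2.996 to 4.93. Those lists drew on all other sequences, including the contigs that the total library lacked. A large fall was not particular to the list. The unlisted sequences at ranks 2, 4 and 5 of the total library had 53447, 45801 and 28959 RPM there. In the hAgo2 library they had 465, 508 and 438 RPM. The most abundant hAgo2 sequence, also unlisted, went the other way, at 5433 RPM against 66.0. Without the 10 most abundant sequences of each library, their middle 95% ran from −5.22 to 1.16, with the microRNAs at −6.01 (percentile 0.1). In that setting each library's 10 were dropped from that library only. Their reads in the other library stayed, so these sequences counted as absent from the first, which enters the values.

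The difference spanned microRNAs of quite different abundance. Bantam-3p, which in flies promotes growth and restrains apoptosis, was the most abundant of the list in both libraries. It took 8846 hAgo2 reads and 398402 total reads, or 2349 and 109984 RPM, and was 46.8-fold lower (log2 ratio −5.55, 95% interval −5.58 to −5.52). Few bantam-3p reads matched the listed form with no mismatch, 5 and 60, and on these alone the log2 ratio was −3.64 (95% interval −4.96 to −2.32). Its 22 nt form TGAGATCATTGTGAAAGCTGAT was the most abundant sequence of the total library with 203818 reads, and had 5168 reads in the hAgo2 library. The 23 nt form TGAGATCATTGTGAAAGCTGATT ranked 3 in the total library with 171387 reads. None of the 5 most abundant sequences of the hAgo2 library matched the list. MiR-184-3p followed with 3297 hAgo2 and 133976 total reads (log2 ratio −5.40), and miR-307-3p with 1106 and 89021 (log2 ratio −6.39). Among the other named microRNAs, miR-2/13 (log2 ratio −4.94), miR-8-3p (−4.93), miR-317-3p (−4.63) and miR-10-5p (−3.60, 156 and 1820 reads), which lies in the Hox gene cluster, were lower by less than the list as a whole. MiR-79-3p (−7.38, 141 and 22583 reads), miR-932-5p (−7.51, 19 and 3331 reads), miR-14-3p (−6.47), miR-279-3p (−6.31) and miR-87-3p (−5.95) were lower by more. For miR-279-3p (254 and 19363 reads) the order against the list turned under stricter matching, and for miR-79-3p it could no longer be told within counting error. Both settings kept few reads. Most of their reads differed from the listed form by a mismatch or a shift, so the few kept say little about the rest. MiR-279-3p was at −3.10 (15 and 124 reads) with no mismatch, where the list was at −5.67. MiR-79-3p was at −5.34 (8 and 312 reads, 95% interval −6.35 to −4.33) with no 5′ shift, where the list was at −5.56. MiR-970-3p (−6.10, or −3.76 on 1 and 13 reads with no mismatch), miR-34-5p (−5.92), miR-7-5p (−5.68) and miR-989-3p (−5.56, 15 and 683 reads) could not be told from the list's share within counting error. As shares of microRNA reads rather than of all reads, 9 of the 16 named microRNAs were lower in the hAgo2 library and 7 higher, from −1.93 to 1.98 on the log2 scale. For 4 of the 16 (miR-34-5p, miR-7-5p, miR-970-3p and miR-989-3p) the 95% interval of this ratio included 0.

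MiR-1-3p, the muscle microRNA, was the 1 microRNA of the 28 that did not pass the 2-fold bound. It fell outside the naming rule and was chosen after its values were seen. It had 104 hAgo2 reads and 83 total reads (log2 ratio 0.27, 95% interval −0.16 to 0.70), a difference within counting error. The next highest log2 ratio of the 28 was −3.60.

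**Figure D2:**
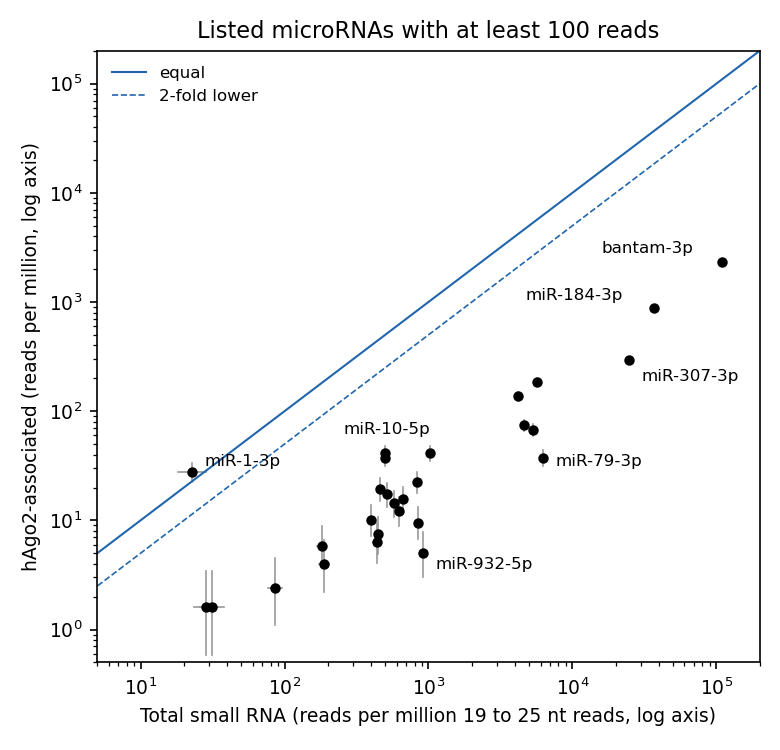
RPM (over 19 to 25 nt reads) of the 28 listed microRNAs with at least 100 reads, total library on the horizontal and hAgo2 library on the vertical log axis; grey bars are exact 95% Poisson intervals of the counts, the solid line marks equal levels and the dashed line a 2-fold lower level. All points but miR-1-3p lie below the dashed line, with bantam-3p at 109984 and 2349.

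MicroRNA reads were spread more widely in length in the hAgo2 library, mostly toward shorter reads. Reads of the list were most often 22 nt long in both libraries, at 45.6% and 47.8%, but 22 and 23 nt together made up 69.8% in the hAgo2 library (95% interval 69.1 to 70.5) and 81.5% in the total library. Reads of 20 nt or shorter made up 10.4% and 6.58%, and reads of 24 nt 5.10% and 2.14%. For miR-2/13 the commonest length was 24 nt in the hAgo2 library and 22 nt in the total library. The share of reads of 22 nt or longer was lower in the hAgo2 library for 14 of the 16 named microRNAs and higher for 2, miR-7-5p (58.7% against 44.6%) and miR-2/13 (93.1% against 92.95%). It was 93.4% against 96.1% for miR-8-3p. Such reads made up 58.2% of hAgo2 and 92.95% of total reads for miR-79-3p, 61.0% and 87.6% for miR-279-3p, 72.6% and 88.2% for miR-307-3p, and 21.1% and 82.1% for miR-932-5p with its 19 hAgo2 reads. Of bantam-3p reads, 93.0% in the hAgo2 library were 22 or 23 nt long (95% interval 92.4 to 93.5), against 95.8% in the total library (95% interval 95.7 to 95.9), with 23 nt at 33.1% and 44.3% and 24 nt at 3.85% and 1.70%, and 0.837% of the hAgo2 ones were 20 nt or shorter (95% interval 0.657 to 1.05).

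Fragments of the expressed gene itself were present in the hAgo2 library. The first 336 nt of the human AGO2 coding sequence, fixed as a query before the data were examined, matched 5554 hAgo2 reads exactly, of which 77.3% were sense (95% interval 76.2 to 78.4) and 80.2% were 20 nt long. Such 20 nt reads began at 357 of the 634 possible positions on both strands. A 92 nt leader of the polyhedrin gene, the very late baculovirus gene whose promoter drives many insect cell vectors, matched 92 reads, 70 of them sense. The total library had 0 reads on either stretch, with an upper 95% limit of 0.000102%. The floor of 3 counts equals 8.28e-05%. The 0.150% of hAgo2 reads on both stretches was 1810-fold higher than this floor in the total library. Counted once per distinct sequence, the hAgo2 share was 0.0825%.

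**Figure D3:**
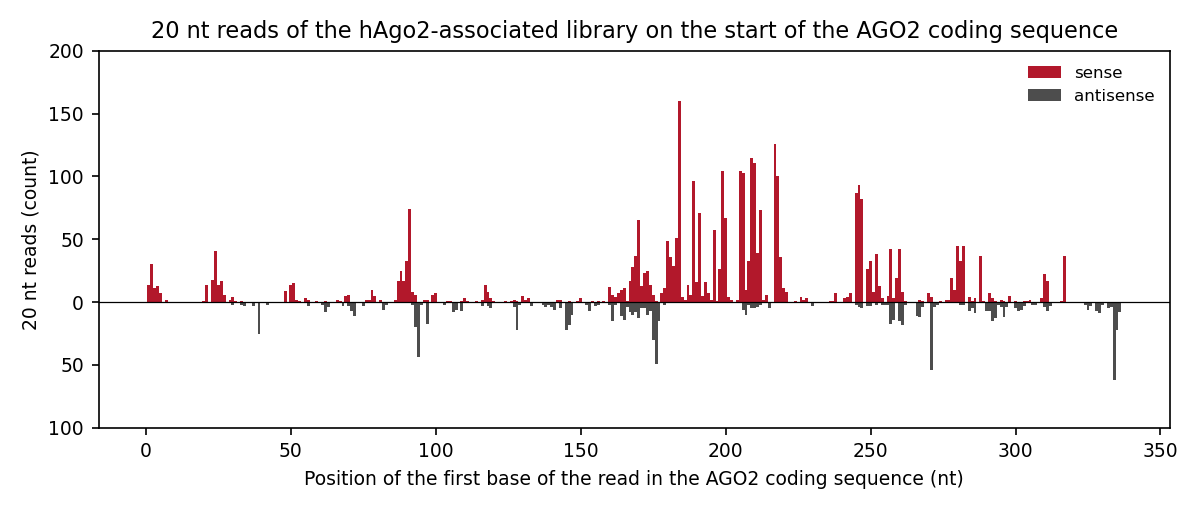
Counts of 20 nt reads of the hAgo2-associated library (1 library) by the position in nt of their first base in the first 336 nt of the AGO2 coding sequence, with sense reads above the line and antisense reads below it. Sense reads made up 77.3% of the reads on this stretch.

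Most hAgo2 reads lay on contigs that were covered on both strands and that the total library lacked. Overlapping 20 and 21 nt reads joined into 1223 contigs of at least 50 nt (117794 nt in all, the longest 742 nt), and the same procedure on the total library gave 316 contigs (23239 nt). Of the hAgo2 contigs, 1113 (109111 nt) had under 1% as many reads in the total library, 14 reads in all. These 1113 contigs held 54.8% of hAgo2 reads of 19 to 25 nt (95% interval 54.7 to 54.8), and 86.0% of those reads were 20 nt long. The contigs were built from 20 and 21 nt reads alone, which favours that length here and in the shares by gene below. The AGO2 stretch fixed beforehand, at 80.2%, is free of this. Each of the 1113 had 20 nt reads on both strands, with a median of 35.9% on the minor strand (quartiles 26.98 and 43.4). A translated search of the hAgo2 contigs covered 785 of the 859 amino acids of human AGO2 at 100% identity. It also covered 456 of 512 amino acids of gp64, the envelope fusion protein of baculoviruses, and all 94 of p10, a very late fibrillar protein, both at 100% identity. Of vp39, the major capsid protein, 248 of 346 amino acids were covered at 99.6% identity. The green fluorescent protein used as a control, and reversed forms of all proteins, gave 0 hits, and contigs of the total library gave 0 hits for every protein. Contigs of AGO2, gp64, p10 and vp39 held 77900, 34937, 16498 and 5060 reads of 19 to 25 nt, against 2062689 on all 1113 contigs. The source of the other contigs was not identified. The assembly and the protein queries were chosen after the reads had been seen.

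The strands were read unequally, and to a different degree by gene. Sense reads made up 76.5% of the 77900 reads on AGO2 contigs (95% interval 76.2 to 76.8), 63.7% of the 16498 on p10 (95% interval 63.0 to 64.4), 61.1% of the 5060 on vp39 (95% interval 59.7 to 62.4) and 55.5% of the 34937 on gp64 (95% interval 55.0 to 56.0). The 20 nt share was 82.1% on AGO2, 78.9% on p10, 84.0% on vp39 and 88.0% on gp64. Over the 1113 contigs, 20 nt reads began with A or U more often than the contigs' own sites, at 36.9% against 27.9% for A and 38.3% against 27.5% for U. They began with G less often, at 9.70% against 21.9%. At position 18, counted from the 5′ end, G or C stood in 70.1% of these reads against 45.2% of sites, the highest share of the 20 positions, ahead of 56.6% at position 19.

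**Figure D4:**
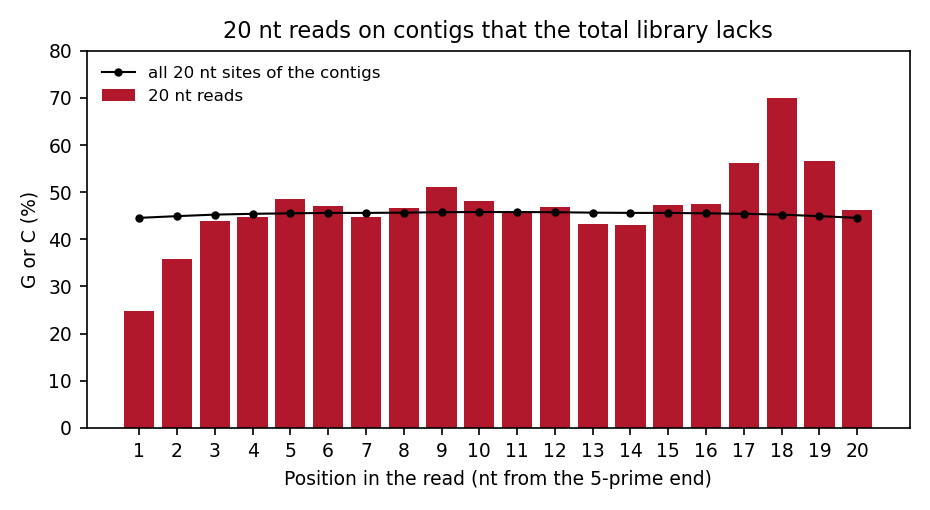
Share of G or C (%) at each position, from the 5′ end, of 20 nt hAgo2 reads on the 1113 contigs that the total library lacked (red bars, reads of 1 library), and the share over all 20 nt sites of both strands of those contigs (black line). The share was 24.8% at position 1 and 70.1% at position 18, against 44.5% and 45.2% of sites.

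The hAgo2 library held many sequences that were not read in the total library. Of all hAgo2 reads of 19 to 25 nt, 13.7% (95% interval 13.7 to 13.8) had their exact sequence in the total library, while 67.8% of total reads had theirs in the hAgo2 library. For 20 nt reads the shares were 7.50% of hAgo2 and 39.97% of total reads, and for 22 nt reads 48.8% and 89.7%. The hAgo2 library was also the more even. Its 100 most abundant sequences held 5.35% of reads, against 51.9% in the total library (log2 ratio −3.28, 95% interval −3.28 to −3.27), or −2.31 on the log2 scale in the 21 to 23 nt window. Over 19 to 25 nt there were 3.68 and 4.68 reads per distinct sequence.

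Structural RNA was counted on a few short stretches. Exact matches to 11 stretches of U6 snRNA, rRNA and tRNA took 0.0344% of hAgo2 reads and 0.147% of total reads (log2 ratio −2.09, 95% interval −2.18 to −2.002), led in both by tRNA-Lys with 745 and 3366 reads. U6 took 356 and 687 reads, and tRNA-Asp 69 and 1076. These stretches are a lower limit on structural RNA. With 2 further rRNA stretches, added after the reads had been seen, the shares were 0.569% and 0.302%, and the direction turned (log2 ratio 0.92). The log2 ratio was −0.017 in the 21 to 23 nt window and −0.70 with each distinct sequence counted once.

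Few reads matched vertebrate microRNAs. The 9 listed took 13 hAgo2 reads and 92 total reads, of which miR-21-5p took 1 and 45, miR-24-3p 1 and 17, miR-103-3p 1 and 12, miR-16-5p 7 and 6, and miR-26a-5p 3 and 5. MiR-20a-5p, the microRNA named in the series title, had 0 hAgo2 reads, below the floor of 3 counts (0.797 RPM), and 4 total reads.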

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

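These values come from reads outside the 19 to 25 nt comparison, and all of these counts were chosen after the reads had been seen. Reads of 26 to 29 nt, the piRNA size range, made up 16.7% of all total library reads (963178), and 0.0756% of hAgo2 reads, whose gel window ended at 25 nt. Of them, 73.7% began with U. Among their 207272 distinct sequences, 44.7% had a partner at 10 nt, a sequence whose first 10 bases were the reverse complement of their own. The shares were 66.1% at 8 nt, 37.8% at 9 nt and 12.05% at 11 nt. No genome was used, so partners were not shown to come from opposite strands of the same site. Words this short also match by chance, the more so at 8 and 9 nt, and that level was not computed. A stood at position 10 in 43.8% of the reads that did not begin with U and in 36.2% of those that did.

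Reads of 15 to 18 nt, below both gel windows, made up 19.96% of total library reads and 5.35% of hAgo2 reads. Of those of 16 to 18 nt, 30.2% in the total library and 9.29% in the hAgo2 library ended in CCA, the end that is added to mature tRNAs, against 1.003% and 0.805% of 20 nt reads. Above the hAgo2 gel window, 30484 hAgo2 reads were 31 to 35 nt long (0.755%), and 27.3% of these held a piece of the 3′ linker.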

How the results depend on the processing

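No paired analysis was possible because each group has 1 library. Matching to a genome was not run because no genome was used, and thinning the total library did not apply because it was the shallower of both in the window. Settings that drop or match contig reads, the wider structural set, the 3-mismatch rule and all settings for 20 nt reads, first-base A and vector reads were added after seeing the data. Values are log2 ratios unless a percent is given, and the cause of a shift was not tested except where the setting itself removes the reads. Counting intervals are narrow at this depth, so 47 values moved beyond them, 4 stayed within and 2 reversed. The 2 reversals were the 21 to 23 nt length share with each distinct sequence counted once (0.0076) and the structural RNA share with 2 further rRNA stretches (0.92). With each distinct sequence counted once, 5′ U was −0.19, microRNA share −2.42, structural RNA −0.70, 20 nt share 0.18, A share 0.46 and vector reads 0.0825%. With at least 2 reads per sequence, length was −2.33, 5′ U −0.44, complexity −3.23, shared sequences 15.1%, 20 nt share 2.08, A share 1.61 and vector reads 0.175%. Without the 10 most abundant sequences, length was −1.46, 5′ U −0.22, microRNA share −5.45, structural RNA −2.62, shared sequences 11.3%, list percentile 0.1, 20 nt share 1.08 and A share 0.96. Each was dropped from its own library only, so the shared sequences and the list percentile count it as absent there. In the 21 to 23 nt window, 5′ U was −0.36, microRNA share −3.84, structural RNA −0.017, complexity −2.31 and A share 1.60. Without microRNA reads, length was −1.67, 5′ U −0.076, 20 nt share 1.35 and A share 1.1002. Without contig reads, length was −1.11, 5′ U −0.41, microRNA share −4.43, 20 nt share 1.28 and A share 1.28, and without reads sharing 14 nt with those contigs −1.21, −0.42, −4.05, 1.27 and 1.28. The microRNA share was −5.67 with no mismatch, −5.46 with 2 and −5.47 with 3 outside the first 8 positions. Structural RNA was −1.72 and vector reads 0.185% with 1 mismatch, complexity was −3.80 for 10 sequences, and shared sequences were 15.7% by the first 18 nt. As shares of microRNA reads, 7 named microRNAs reversed because the common fall cancels: bantam-3p (0.030), miR-10-5p (1.98), miR-184-3p (0.18), miR-2/13 (0.64), miR-317-3p (0.95), miR-8-3p (0.64) and miR-989-3p (0.014). With no mismatch or no 5′ shift, all 31 values of the 16 named microRNAs stayed below −1, from −7.79 to −3.10. Bantam-3p (−3.64), miR-279-3p (−3.10) and miR-970-3p (−3.76) were much less low with no mismatch, on the few reads that matched their listed form exactly. MiR-87-3p had 0 hAgo2 reads and 1 total read with no mismatch, so nearly all its reads differed from the listed form.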

Other observations

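The tests of trimming, of shared 20 nt RNAs, of missed microRNA variants and of strand choice, and the structural fragments on the 2 further rRNA stretches, were chosen after the result was seen, as were the reads sharing 14 nt with contigs and the comparison of sequences found in both libraries. Each pattern rests on 1 library per group. The hAgo2 cells also differed from the control cells in making the recombinant protein. Reads on contigs of the baculovirus genes gp64, p10 and vp39 were found in the hAgo2 library alone. What hAgo2 bound and what the cells contained, baculovirus RNA included, therefore cannot be separated.

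The excess of 20 nt reads was not explained by the assembled new templates alone, and whether trimming added to it stays open. Trimming of longer reads is argued against for bantam-3p itself, of which 0.837% of hAgo2 reads were 20 nt or shorter. Over all listed microRNAs this share was 10.4%, against 6.58% in the total library. Reads of 22 nt or longer were a lower share in the hAgo2 library for 14 of the 16 named microRNAs and a higher one for 2. For miR-79-3p they made up 58.2% against 92.95%. Bantam-3p alone cannot decide for other reads, because how linkers were trimmed is not known. Of 20 nt hAgo2 reads, 7.50% had their exact sequence in the total library. This cannot tell how many came from RNAs that the total library also holds. Contigs chosen as lacking there capped the value, and 74.3% of hAgo2 and 77.5% of total distinct sequences were seen only once. Contigs that the total library lacked held 64.4% of the 20 nt hAgo2 reads, and only those of AGO2, gp64, p10 and vp39 were identified. Outside all these contigs the 20 nt share was still 2.43-fold that of the total library. It was 2.40-fold without any read sharing 14 nt with a contig, though reads of unassembled templates stay in both values. Among 51186 sequences found in both libraries, microRNAs left out, the 20 nt share was 40.9% of hAgo2 reads and 18.03% of total reads; what remains stays open, and no biological explanation was tested.

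The scarcity of microRNA reads on hAgo2 is not explained by dilution by the assembled contigs alone. Outside the contigs that the total library lacked, the microRNA share was still 21.6-fold lower, and it was 16.5-fold lower without reads sharing 14 nt with them. Assembly was incomplete, covering 71.7% of vp39 and 89.1% of gp64, so reads of unassembled templates stay in these shares. The dilution left in them is not known. Variants missed by the matching are argued against too, since the share was 44.3-fold lower with up to 3 mismatches. Whether insect microRNAs reach the human protein poorly, or whether the cells that made it held fewer microRNAs, stays open in these libraries.

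The high share of A at the first base is not explained by template composition alone, and its cause stays open. Reads of 20 nt on contigs began with A 1.32 times as often as the contigs' sites, and with U 1.39 times as often, so the excess over the templates was not particular to A. An end preference of linker ligation cannot be told apart as a source of this excess over templates. Structural RNA fragments of the hAgo2 library began with A 1.18 times as often as their templates (95% interval 1.07 to 1.29). That lay below the 1.32 of contig reads, the outcome predicted beforehand without a shared end preference. But those of the total library did so 1.39 times as often, and fragments of the 2 further rRNA stretches 1.65 and 1.62 times as often in the hAgo2 and total libraries. For the difference between libraries (35.3% against 13.9%), these fragments showed no clearly higher excess in the hAgo2 library, on 1 library each. Choice of the strand with the weaker 5′ pair, were the reads from 20 nt duplexes with 2 nt overhangs, would put G or C at position 18, where 70.1% of 20 nt contig reads had it. This too cannot be told apart, because such duplexes were not seen as an excess of pairs (at their 18 nt overlap, contig reads paired least, 122755 against 146160 to 192619 at other overlaps of 8 to 30 nt, which the base shares at positions 1 and 18 would themselves lower) and because, of 20 nt sequences found in both libraries with at least 10 reads together, microRNAs and contigs left out, the median log2 ratio was −0.32 for A (quartiles −2.38 and 1.34) and −0.64 for G (−2.38 and 1.06), above −1.28 for U and −2.004 for C.

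Of the hAgo2 reads assigned to miR-1-3p, 10.6% carried a mismatch (11 of 104, 95% interval 5.40 to 18.1), and 4.82% of the total reads did (4 of 83, 95% interval 1.33 to 11.9), a difference within counting error.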
